A study of Mus musculus with 2 samples.

How the data were processed

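Gene expression was measured in macrophages of the mouse colonic lamina propria, the connective tissue layer under the gut epithelium, with 1 array for mice that drank water and 1 array for mice that received 3% (wt/vol) dextran sulfate sodium (DSS) in their water, each for 5 days. DSS is a polymer that injures the colon lining and is widely used to induce colitis in mice. Per the labels' protocols, cells were sorted by flow cytometry as positive for CD45, IAb (an MHC class II molecule), CD11b and F4/80 and negative for CD103, and 100 ng of total RNA was amplified into biotin-labelled cRNA for hybridisation by the Affymetrix procedure. The labels do not say how many mice were pooled for an array.

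The authors deposited 1 table of log2 signals for 35556 probe sets on both arrays. RMA (robust multi-array average: background correction, quantile normalisation and median polish of probes into probe sets, on the log2 scale) is named in the submitters' processing notes, with no version. The RMA settings, the array design and a genome build are not given in the sources used here. The values were used as deposited, without centring. RMA compresses differences between dim probe sets, and its quantile step, where used, removes a global shift between arrays. The table holds no detection calls, so a dim signal cannot be told from background, and a scan or hybridisation batch cannot be separated from the treatment with 1 array in each.

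Genes were named from the platform annotation table, which lists 21789 probe sets with 1 gene symbol and 1621 with several. The other 12146 probe sets had no listed gene, 6617 of them with identifiers below the lowest listed one. Those 6617 were kept out of the array medians, which rest on 28939 probe sets. Of the probe sets with 1 symbol, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier and 91 did not. No symbol needed an update, and no coordinates were taken from that table.

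A gene took the value of its probe set with the highest mean signal. Of 19938 genes, 18939 had 1 probe set. A gene entered counts and list medians when at least 1 of the 2 arrays had it at or above that array's median, which 11163 genes did. Probe sets with several symbols were not used to name genes. The difference was the log2 DSS signal minus the log2 control signal, and genes were counted at a fixed size of 2-fold. With 1 array per group there is no replicate error, so no standard error or p-value is given, and every difference compares these 2 arrays, not the conditions. The number of arrays limits the precision. As a yardstick, the robust SD of the differences was 0.39 over the 11163 genes. In 641 genes with at least 2 passing probe sets of different values, the pooled SD between probe sets of a gene was 0.28, which covers probe noise only.

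Before the data were examined, 32 gene lists with 667 entries were fixed. Of these entries, 62 had no probe set with 1 gene and were left out of the list medians. Each list is described by its median difference and by the percentile of that median among 10000 random gene lists of the same size, drawn with replacement within 20 bins of mean signal. A list was said to stand apart below the 2.5th or above the 97.5th percentile. This is a description of these arrays, and lists with fewer than 3 genes past the signal rule have no percentile. The rule for named genes was also fixed beforehand. It took the 12 genes furthest in each direction (without predicted genes and immunoglobulin or T cell receptor segments), the 5 antigens of the sort, the 4 members of each list with the largest differences plus the member furthest the other way, and all reference and sex-linked genes. Genes from outside the rule are named as chosen after their values were seen.

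Alternatives covered the scaling of the arrays (median centring, loess centring with a span of 0.4), the probe set chosen for a gene, the signal rule, a floor at the 25th percentile of all values, sizes of 1.5-fold and 3-fold, the mean of a list and unmatched random lists. The steps were tested on simulated data built from the control array with noise of the yardstick size. In these, 100% of genes raised by a log2 value of 2 and 97.1% of those lowered by it were recovered. Changes were put only into genes with 1 probe set and a control signal at or above the median, so recovery from dimmer signals was not tested. Of 11146 unchanged genes, 1.31% passed 2-fold, which follows from the noise setting and is not an error rate of the real comparison. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.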

Results

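The series compared inflammatory with control macrophages of the colon, to ask how gene expression in these cells differs in colitis. Of the 2 arrays, 1 held RNA of lamina propria macrophages from mice that drank water and 1 held RNA of the same sorted population after 5 days of 3% DSS. Over the 28939 probe sets used for array medians, the median signal was 5.70 on the control array and 5.62 on the DSS array (log2). Both arrays correlated with r = 0.975 across these probe sets, which are not independent replicates. There were no replicate arrays, so the values below carry no replicate error and no test between conditions was possible. Log2 signals and differences are given for each gene, and a fold is 2 to the power of the difference.

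The DSS array had genes of the neutrophil and monocyte lists far above the control array, and it had genes of the resident intestinal macrophage list far below it. Of 11163 genes past the signal rule, 445 (3.99%) were at least 2-fold higher in DSS, 338 (3.03%) were at least 2-fold lower and 10380 lay between. At least 4-fold differences were found for 125 genes in the higher direction and 58 in the lower, and at least 16-fold differences for 26 and 2. The largest difference was that of Mmp8 (probe set 10583100), the neutrophil collagenase, at 4.82 in control and 11.47 in DSS, which is 100.3-fold. Stfa3, a stefin, followed at 66.1-fold, Lcn2, the iron-siderophore binding lipocalin, at 64.4-fold and Ly6g, the surface antigen used to identify mouse neutrophils, at 62.8-fold. Chil3, a chitinase-like protein of myeloid cells, was 59.9-fold higher, Saa3, an acute-phase apolipoprotein, 57.7-fold, and Cxcr2, a chemokine receptor of neutrophils, 56.4-fold. Ngp, a neutrophil granule protein, Il1f9 (the cytokine IL-36 gamma) and Ly6i were 52.2-fold, 39.9-fold and 33.0-fold higher, and the secreted proteins Dcpp3 and Dcpp2 were 31.4-fold and 28.5-fold higher. Among these 12 genes, only the control signal of Saa3 (5.74) reached the control array's median of 5.70, and only just. The median is not a detection limit, so the folds of all 12 start from dim signals that cannot be told from background.

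**Figure D1:**
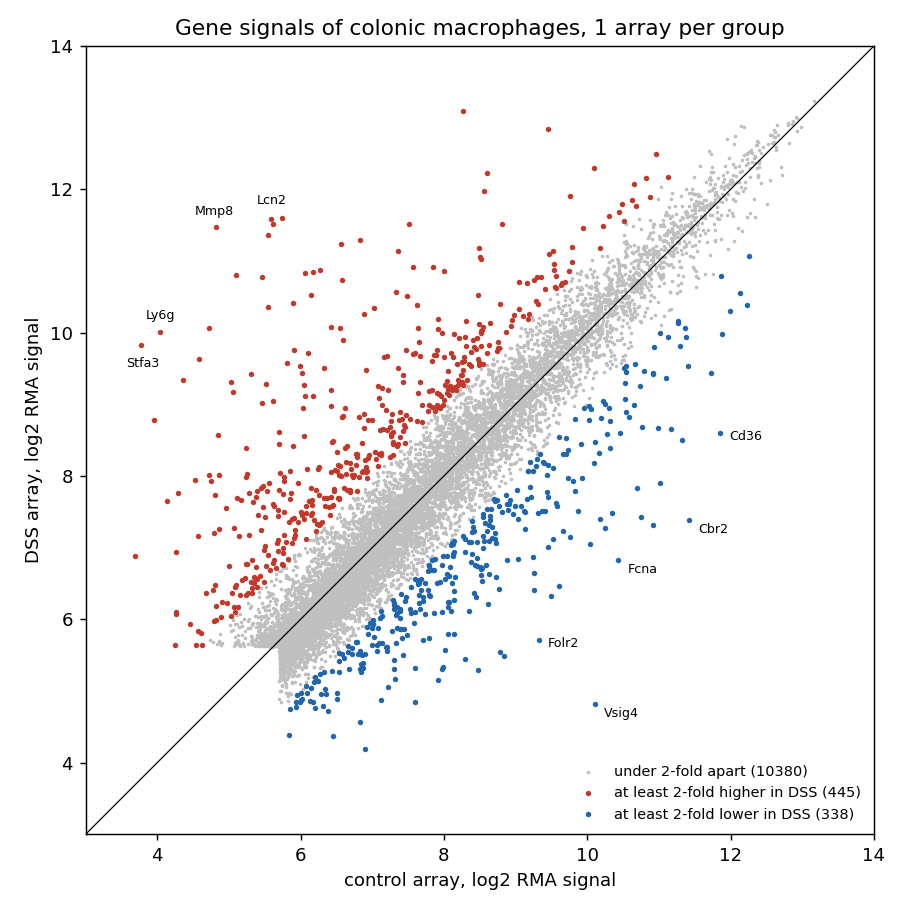
Log2 RMA signal of each of the 11163 genes past the signal rule on the control array (x axis) and the DSS array (y axis), 1 array per group, with equal signals on the black line. The 445 genes at least 2-fold higher in DSS (red) include Mmp8 at 11.47 against 4.82, and the 338 at least 2-fold lower (blue) include Vsig4 at 4.82 against 10.11.

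In the lower direction, Vsig4 (probe set 10605848), a complement receptor of tissue macrophages, had the largest difference, at 10.11 in control and 4.82 in DSS, or 39.2-fold lower. Cbr2, a carbonyl reductase, was 16.4-fold lower. Folr2, a folate receptor of resident macrophages, Fcna, the lectin ficolin A, and Lyve1, a hyaluronan receptor, were 12.3-fold, 12.2-fold and 12.2-fold lower. The scavenger and lectin receptors Cd209f, Cd163, Cd36 and Colec12 were 10.3-fold, 9.95-fold, 9.49-fold and 9.39-fold lower. Chp2 was 9.12-fold lower and the small heat shock protein gene Hspb1 8.88-fold. Timd4, a phosphatidylserine receptor of long-lived macrophages, read 9.50 in control and 6.33 in DSS. All 12 had control signals above the control array's median. The DSS signals of Vsig4, Cd209f, Colec12 and Chp2, however, were below the DSS array's median and cannot be told from background, so their folds are not exact. The DSS signal of Folr2 (5.71) lay just above that median of 5.62, and its fold is limited likewise.

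The antigens of the sort were present on both arrays, with no difference of 2-fold. Ptprc, which encodes CD45, read 11.54 in control and 11.94 in DSS, and H2-Ab1, the IAb beta chain, 11.99 and 12.13. Itgam, which encodes CD11b, read 9.59 and 10.19. Adgre1, which encodes F4/80, read 11.65 and 10.82, a 1.77-fold lower value in DSS. The 4 antigens past the signal rule had a median difference of 0.27. Itgae, which encodes CD103, the antigen the sort excluded, was below the median of both arrays at 4.89 and 4.91. All 15 measured genes of the MHC class II and co-stimulation list lay within 2-fold, with a median difference of 0.14 at the 77.5th percentile of random lists. Cd274, H2-Oa, Cd80 and Icosl had differences of 0.82, 0.61, 0.54 and -0.38. The sign of this list's median and that of H2-Ab1 turned under loess centring.

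Genes of the neutrophil list had the highest median difference of all lists. Of 19 members past the signal rule, 17 were at least 2-fold higher in DSS, 0 were at least 2-fold lower and 2 lay between, with a median of 3.50 that exceeded all 10000 random lists. The 4 largest were Mmp8, Stfa3, Lcn2 and Ly6g, and Mpo, the myeloperoxidase of early granulocytes, read 5.35 in control and 5.64 in DSS. Among lists with at least 3 passing genes, the monocyte list followed. It had 13 of 17 members at least 2-fold higher, 1 lower and a median of 2.19, also above all random lists. Chil3 led it, followed by Hp, the haemoglobin-binding protein haptoglobin, at 27.2-fold, Ifitm6 at 25.4-fold and Trem1, an activating receptor of monocytes and neutrophils, at 24.4-fold. F13a1, which encodes coagulation factor XIII subunit A, went the other way and was 3.68-fold lower.

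The resident intestinal macrophage list lay below the control. Of its 28 members, 17 were at least 2-fold lower in DSS, 0 were at least 2-fold higher and 11 lay between, with a median of -1.19 that was below all random lists. Folr2, Lyve1, Cd209f and Cd163 had the largest differences. On the same DSS array the neutrophil list had a median of 3.50. Every resident list member past the signal rule had a negative difference, and Axl, a receptor tyrosine kinase for apoptotic cell uptake, had the smallest, at 8.71 in control and 8.43 in DSS. The lysosome and phagocytosis list was also lower, with a median of -0.40 below all random lists, beside the same neutrophil median. Of its 29 members 3 were at least 2-fold lower (Cd36; Atp6v0d2, a proton pump subunit, 3.40-fold; Gpnmb, 2.57-fold) and 0 were at least 2-fold higher. Ctsk, a cathepsin, lay furthest the other way, at 5.51 in control and 6.45 in DSS.

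**Figure D2:**
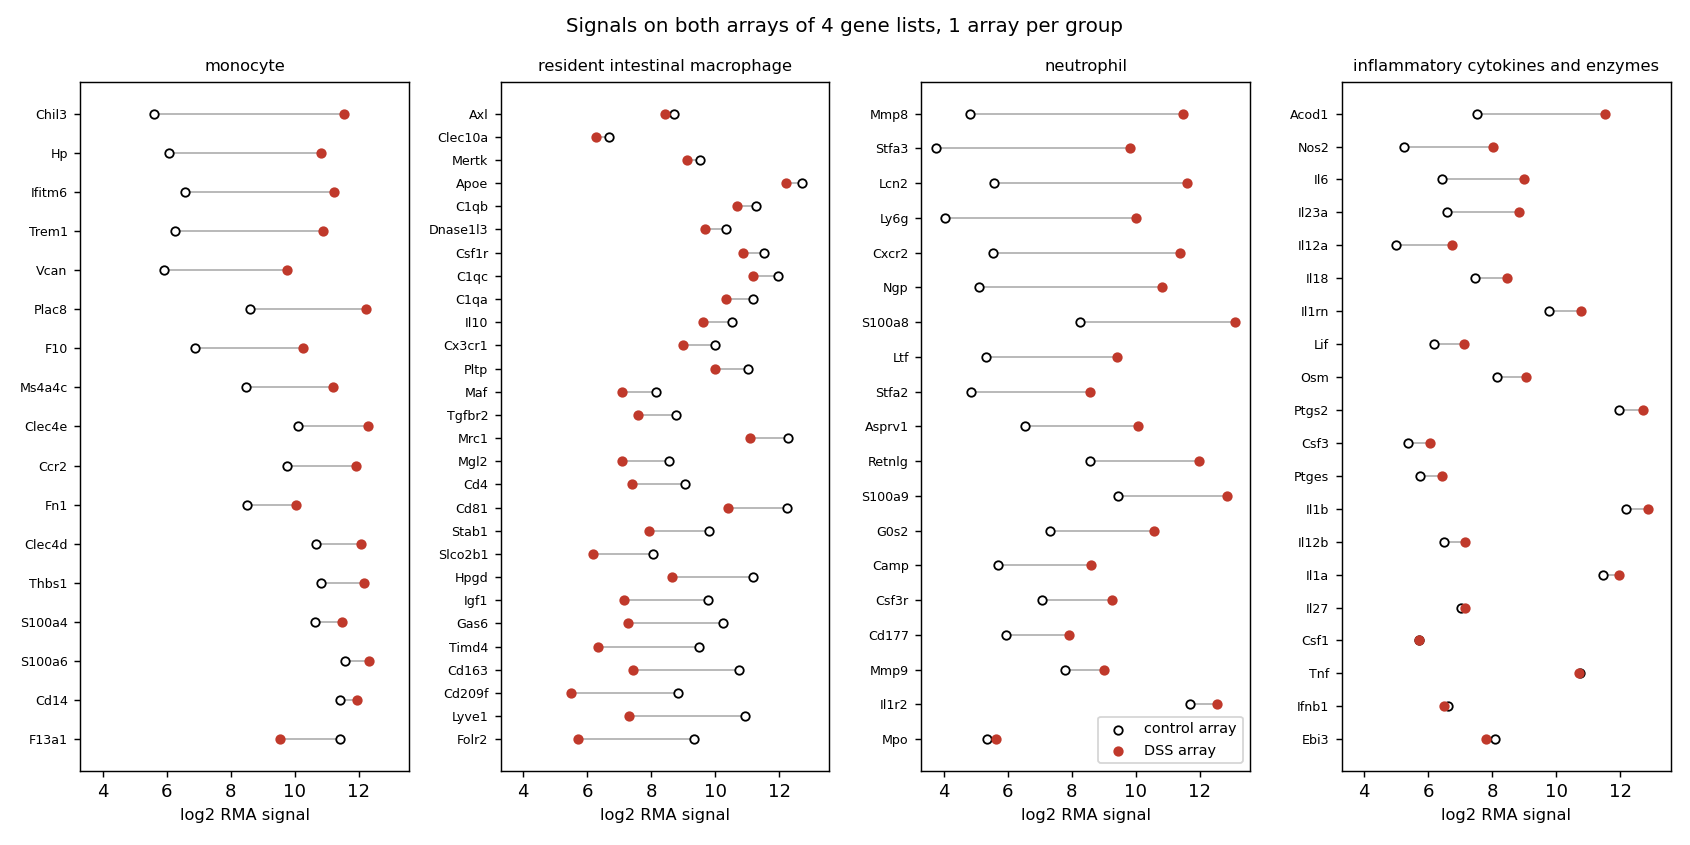
Log2 RMA signal (x axis) of the members past the signal rule of 4 lists, with the control array as open circles and the DSS array as red circles, 1 array per group. The DSS signal exceeds the control signal in 16 of 17 monocyte and 19 of 19 neutrophil genes and lies below it in 28 of 28 resident macrophage genes.

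Inflammatory mediators were higher in DSS as a list, by less than the neutrophil list. Of the 20 inflammatory cytokine and enzyme genes, 6 were at least 2-fold higher, 0 were at least 2-fold lower and the median was 0.72, above all random lists. Acod1, which makes itaconate, read 7.52 in control and 11.52 in DSS. Nos2, the inducible nitric oxide synthase, was 6.79-fold higher, from a control signal under the array's median. Il6 was 5.91-fold higher and Il23a, the p19 subunit of interleukin 23, 4.74-fold, while Ebi3 read 8.07 in control and 7.82 in DSS. Tnf and Il1b, chosen after their values were seen, read 10.74 and 12.18 in control and 10.72 and 12.86 in DSS. The interferon-stimulated list had 12 of 25 members at least 2-fold higher, 0 lower and a median of 0.89, above all random lists. The guanylate-binding protein gene Gbp5 was 5.93-fold higher, the nucleic acid sensor Zbp1 4.82-fold, the GTPase gene Irgm1 4.27-fold and the transcription factor Irf7 3.10-fold, and Bst2 read 9.30 in control and 9.06 in DSS. Both lists were higher beside a neutrophil list median of 3.50 on the same arrays.

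Chemokine genes differed in both directions, with 4 of 24 at least 2-fold higher, 7 at least 2-fold lower and a median of -0.32, below all random lists, beside the neutrophil median of 3.50. Ccl5 and the interferon-inducible T cell attractant Cxcl9 were 7.22-fold and 6.54-fold higher. Ccl24, an eosinophil attractant, and Ccl7, a monocyte attractant, were 5.29-fold and 4.24-fold lower. In the pattern recognition list, 9 of 25 members were at least 2-fold higher, 1 was lower and the median was 0.67, above all random lists. Trem1 led, with Trem3 at 11.8-fold, from a control signal under the array's median, and the C-type lectin Clec4e at 4.58-fold. Cd36 was the lower member, again beside the neutrophil median of 3.50. The inflammasome list had a median of 0.44 at the 99.7th percentile. Naip2 and Gsdmd were 2.70-fold and 2.24-fold higher, Il18 read 7.45 in control and 8.46 in DSS, and P2rx7, the ATP-gated channel, was 3.08-fold lower. This list no longer stood apart when its mean of 0.37 was used (93.5th percentile). The list of IL-10, TGF-beta and restraint of NF-kB had a median of 0.04 at the 36.3rd percentile, and of -0.06 under loess centring. Irak3, an inhibitor of Toll-like receptor signalling, was 2.31-fold higher, Tgfbr2 was 2.26-fold lower, Il10 read 10.52 in control and 9.62 in DSS and Nfil3 read 11.16 and 11.86.

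Genes linked to alternative activation also divided. Of 20 members, 3 were at least 2-fold higher, 7 were at least 2-fold lower and the median was -0.39, at the 0.02nd percentile, beside the neutrophil median of 3.50. Chil3 and Arg1, which encodes arginase 1, were 59.9-fold and 10.8-fold higher, both from control signals under the array's median. Cd163 and Retnla, a secreted resistin-like protein, were 9.95-fold and 7.11-fold lower. Matrix remodelling and growth factor genes had 9 of 28 members at least 2-fold higher and 5 at least 2-fold lower. Mmp8, Inhba (the activin A subunit) and Adam8 were 100.3-fold, 11.6-fold and 4.41-fold higher, and Igf1 was 6.15-fold lower. The median of this list was 0.24 at the 98.8th percentile, and -0.01 at the 36.2nd percentile once the genes it shares with the neutrophil and monocyte lists were left out, an alternative chosen after seeing the data.

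Among metabolic lists, glycolysis and hypoxia genes were higher in DSS, with 8 of 20 at least 2-fold higher, 0 lower and a median of 0.88, above all random lists, beside a neutrophil list median of 3.50. Egln3, an oxygen-sensing prolyl hydroxylase, was 5.61-fold higher, from a control signal under the array's median. The lactate exporter Slc16a3 was 4.38-fold higher, the glucose transporter Slc2a1 3.38-fold and Ero1a 3.12-fold, while Pfkfb3 read 9.86 in control and 9.56 in DSS. All 28 oxidative phosphorylation genes lay within 2-fold, with a median of 0.20 at the 88.7th percentile. Ndufb3, Cox7b, Cycs and Ndufs1 had differences of 0.63, 0.59, 0.55 and 0.53, and Ndufa5 one of -0.26. Oxidative burst and stress genes had a median of 0.27 at the 95.6th percentile. In that list the cystine transporter Slc7a11 was 8.17-fold higher and Sod2 2.67-fold higher, and the haem-degrading enzyme gene Hmox1 and the metallothionein gene Mt2 were 3.37-fold and 2.63-fold lower. Lipid and cholesterol genes had a median of 0.04 at the 68.3rd percentile, which turned to -0.25 under the stricter signal rule, where the list stood apart as lower (0.97th percentile). Its members differed in both directions, with the fatty acid binding protein genes Fabp4 and Fabp5 3.43-fold and 3.07-fold higher and Pltp 2.03-fold lower. Scd1 was 2.28-fold higher, from a control signal under the array's median.

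Cell cycle genes had a median of -0.40 at the 0.03rd percentile, with 0 of 23 members at least 2-fold apart, beside a neutrophil list median of 3.50. The replication helicase genes Mcm6, Mcm7 and Mcm2 had differences of -0.79, -0.61 and -0.60, and the mitotic kinase gene Aurka one of 0.82. The immediate early and heat shock list had a median of -0.22 at the 0.06th percentile, with 6 of 28 members at least 2-fold lower and 1 higher, beside the same neutrophil median. The chaperone genes Hsph1, Dnajb1 and Hspa1a were 4.89-fold, 3.63-fold and 3.22-fold lower, Jun was 2.80-fold lower and Nr4a2 was 2.09-fold higher.

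Lists of other cell types with at least 3 passing genes had medians closer to 0 than those of neutrophils and monocytes. The dendritic cell list had a median of 0.47 at the 99.9th percentile, with Cd24a and Naaa 2.48-fold and 2.31-fold higher, Ccr7 at a difference of 0.95 and Siglech, a plasmacytoid marker, 2.70-fold lower. It no longer stood apart by its mean of 0.34 (94.0th percentile) or under the stricter signal rule, with 0.36 (92.2nd percentile). The epithelial list had a median of 0.09 at the 96.8th percentile, with 3 of 18 members at least 2-fold higher. These were the antimicrobial lectin genes Reg3b (19.5-fold) and Reg3g (5.32-fold), both from control signals under the array's median, and Fabp2 (2.64-fold). Car1 had a difference of 0.83 and Cdx1 one of -0.49. By its mean of 0.51 (99.9th percentile) and without a signal rule (99.6th percentile) the list stood apart as higher. The T and NK cell list had a median of -0.14, the B and plasma cell list -0.23, the fibroblast, muscle and endothelial list -0.16 and the eosinophil list -0.12, none of which stood apart. Without a signal rule the T and NK median turned to 0.04 and stood apart as higher (98.4th percentile), and the mean of the fibroblast, muscle and endothelial list was 0.02. Only 6 of the 18 measured T and NK genes passed the signal rule, and Cd3d, Cd3e and Cd3g were under the medians of both arrays. Among the 6, Cd28 and Cd2 were 7.20-fold and 2.41-fold lower, Gzma was 3.21-fold higher and Icos read 6.82 in control and 6.56 in DSS. The DSS signal of Cd28 and the control signal of Gzma were under the medians of their arrays. Tnfrsf17 was 2.25-fold lower, with a DSS signal under the array's median, and Igha, Derl3 and Mzb1 had differences of -0.87, -0.48 and 0.49. Outside the measured genes of the list, immunoglobulin kappa probe sets assigned to several genes were examined after the values were seen. They had a median of -1.25, with 7 of 10 at least 2-fold lower and 1 at least 2-fold higher. Some are shared with Igkc, a list entry that had no probe set of its own. The 6 heavy or lambda sets assigned to several genes had a median of -0.66, with 0 at least 2-fold apart. Mgp, Pecam1, Cdh5 and Dcn had differences of 0.85, 0.85, 0.59 and -0.58, and the eosinophil genes Siglecf, Prg2, Ccr3 and Alox15 differences of -0.24, -0.16, -0.09 and -0.02, the last of which turned positive under both centrings. Only 2 mast cell genes passed the signal rule, Hdc, the histamine-forming enzyme, at 25.4-fold higher and Kit at a difference of 0.96, and the 8 below it had differences of -0.39 to 0.34. The glial list (Sox10, -0.20) and the erythroid list (Slc4a1, -0.07, positive under both centrings) each had 1 passing gene.

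Reference genes had a median difference of 0.07, which was -0.12 under loess centring and had a mean of -0.01. Actb, B2m, Ppia, Eef1a1, Hprt, Sdha, Gusb, Polr2a, Tbp and Ywhaz had differences of 0.09, 0.13, 0.07, 0.07, -0.11, -0.08, -0.19, -0.18, 0.24 and 0.28, and other probe sets of Ppia and Ywhaz differed in sign. Actb, B2m, Ppia and Eef1a1 turned negative under loess centring, and Sdha turned positive under median centring, so no direction is given for them. Pgk1, also a glycolysis gene, had a difference of 0.89, and the transferrin receptor gene Tfrc was 2.58-fold lower. The ribosomal protein list had a median of 0.18 at the 82.8th percentile, with 0 of 22 genes at 2-fold. Rps9, Rpl27, Rpl5, Rps10 and Rpl14 had differences of 0.50, 0.26, 0.26, 0.25 and -0.13. Xist was below the median of both arrays (4.32 and 4.27), and the Y-linked genes Eif2s3y, Kdm5d and Uty were above it on both, with differences of 0.30, 0.30 and 0.05 and a list median of 0.30. Of the 29 lists with a percentile, 9 stood apart as higher and 6 as lower. By chance 1.45 would do so if the genes of a list varied independently, as those of the random lists do. Genes of a fixed list can vary together, which makes more lists stand apart, so 1.45 is no measure of chance here. Lists that share genes are also not independent of each other.

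**Figure D3:**
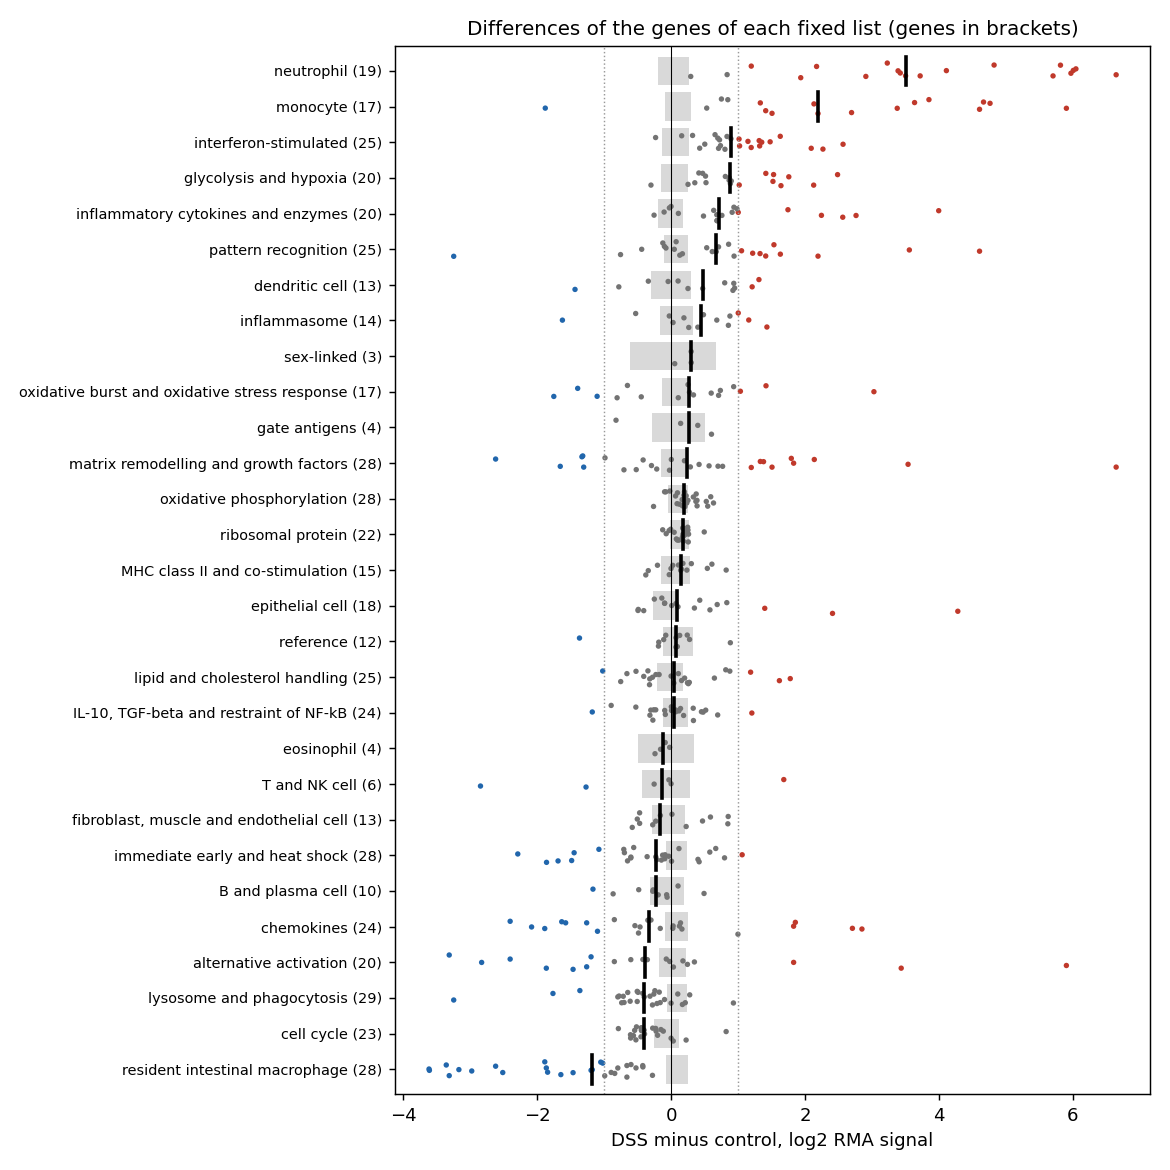
DSS minus control difference in log2 RMA signal (x axis) for each gene past the signal rule (points, red at least 2-fold higher and blue at least 2-fold lower) in the 29 lists of 3 or more genes, with the list median as a black bar and the central 95% of medians of 10000 random lists as a grey box. The medians run from -1.19 for resident intestinal macrophage genes to 3.50 for neutrophil genes.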

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

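The tests for neutrophil RNA and handling were chosen after the values had been seen. Those for dilution and salivary RNA were changed after that. Those for sort purity, pancreatic RNA and colon epithelial RNA were chosen before, but not blind to the patterns, which came from these arrays. The sort purity and colon epithelial tests also rest on medians of the fixed lists given above. Genes named only in this part were chosen after their values were seen. With 1 array per group, a biological effect of DSS stays open and untested for each pattern below.

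Neutrophil transcripts were far higher on the DSS array (list median 3.50), although the sort required F4/80 and IAb, and S100a8 and S100a9 read 8.27 and 9.45 in control and 13.10 and 12.85 in DSS. A second list of neutrophil genes adds no support for neutrophil RNA, since 10 of its 16 measured genes are in the first list and only Slc2a3 and Dgat2 (median 1.90) lay outside it, past the signal rule and below the 60 highest genes. A general loss of sort purity would have raised other cell types alike. The highest median of the T and NK, B and plasma, epithelial and stromal lists, however, was 0.088. A difference between the arrays cannot show RNA of other cells that both sorts held. Of the measured genes, 12 of 18 T and NK and 5 of 15 B and plasma genes were below the signal rule. So were 8 of 26 epithelial and 7 of 20 stromal genes. Others were bright on both arrays, such as Jchain (10.79 in control and 10.52 in DSS), Dcn (9.66 and 9.08) and Krt8 (7.97 and 8.05). The median over all 10 measured mast cell genes was 0.22 (Hdc 4.67, Kit 0.96, the 8 below the signal rule -0.39 to 0.34). Of 10 immunoglobulin kappa probe sets with several genes, 7 were at least 2-fold lower in DSS and 1 higher. The 6 heavy or lambda sets with several genes were all within 2-fold, with a median of -0.66. In the other direction, the dendritic cell list, which the test did not include, had a median of 0.47 at the 99.9th percentile, though its mean did not stand apart. The epithelial list stood apart as higher by its mean of 0.51, and the epithelial and the T and NK lists did so without a signal rule (medians 0.088 and 0.04). Amylase probe sets, given below, were also far higher, so some RNA of other cells is not excluded. Whether neutrophils entered the gate or macrophages and monocytes of the inflamed colon may themselves have carried these transcripts was not decided by these arrays.

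Resident macrophage transcripts were lower on the DSS array. Dilution of all macrophage RNA by cells without such transcripts would have lowered genes common to all macrophages by a similar factor. The median of 17 pan-macrophage genes, however, lay 1.55 above that of all 26 resident genes (bootstrap 95% interval over genes 0.97 to 2.32). The interval treats genes as independent and covers the spread between genes only, not that between arrays or mice. The 2 shared genes Csf1r and Mertk were left out of both. Dilution by cells that carry pan-macrophage transcripts cannot be addressed in this way, and Cd14 is also on the monocyte list (median 2.19). H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median difference of 0.05, but the sort required IAb, so these genes cannot decide the question. Adgre1, Csf1r, Cd68, Lgmn and Mertk had differences of -0.82, -0.66, -0.61, -0.49 and -0.42. The highest pan-macrophage genes were Fcgr4, Fcgr1, Cyba and Cd14 at 0.98, 0.83, 0.60 and 0.53. On these 2 arrays, the gap argues against dilution by cells without pan-macrophage transcripts as the whole cause. Dilution by cells that carry them stays open, as does a partial dilution. A heat shock and immediate early response to handling of the control sort cannot be separated from a treatment effect with 1 array per group. The list had a median of -0.22 with members in both directions. Its 5 measured heat shock genes, however, were all lower (Hsph1 -2.29, Dnajb1 -1.86, Hspa1a -1.69, Hsp90aa1 -0.71, Hspa8 -0.09), as were Hspb1, Bag3 and Hspa1l outside it (-3.15, -2.45 and -2.05), beside the resident genes. The probe set that Hspa1a shares with Hspa1b, a list entry without a probe set of its own, read 11.45 in control and 8.60 in DSS. A change of macrophage composition or state in DSS remains open.

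Probe sets that list several genes stayed outside the gene counts. Of the 867 past the signal rule, 39 were at least 2-fold higher in DSS. Another 11 were at least 2-fold lower, 7 of them immunoglobulin kappa sets (median -1.25 over all 10 such sets). The lowest was the set shared by Hspa1a and Hspa1b, at -2.86. The furthest were 6 probe sets shared by Amy2a2, Amy2b and Amy2a5, with only 3 distinct values. They read 3.57 to 3.92 in control and 10.08 to 10.25 in DSS, with a median difference of 6.37 over the 3 distinct values. No single amylase gene is named from them, and Dcpp3 and Dcpp2 were also higher. Pancreatic RNA stays open, since 3 of 14 passing acinar genes were at least 2-fold higher (Cpb1, Ctrb1 and Rnase1). The median of 0.46 over the 14 lay above all random lists, but below the 2-fold that the test asked for. Over all 22 measured acinar genes the median was 0.39. Salivary gland RNA stays open, since 9 of 13 measured genes without Dcpp1 were below the signal rule and the other 4 had a median of 0.90. These were the basal keratin genes Krt14 and Krt5 at 1.76 and 1.35 from control signals under the array's median, Amy1 at only 0.45 and Aqp5 at -0.04. Over all 14 measured salivary genes, with Dcpp1, the median was 0.19. Colon epithelial RNA as the whole source was argued against by a median of 0.088 over 18 genes, although Reg3b had a difference of 4.28. Cross-hybridisation of these probe sets was not tested.

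Of the other probe sets outside the counts, 83 of 2088 with no listed gene were at least 2-fold higher in DSS and 36 were at least 2-fold lower. Among the probe sets with identifiers below the lowest listed one, 397 of 3412 (11.6%) were at least 2-fold higher and 128 (3.75%) at least 2-fold lower.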

How the results depend on the processing

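The alternative that left out the genes of the neutrophil and monocyte lists was chosen after seeing the data, and the others were planned. At 1.5-fold, 1100 genes were higher and 982 lower, and at 3-fold 183 and 118. Under the other 8 settings 358 to 522 genes were higher and 247 to 343 lower, and without the neutrophil and monocyte genes 415 and 337. Median centring moved the median of all genes by 0.08 and gave 522 higher and 290 lower. Of 29 lists, 21 kept their side of the random lists under each planned setting that gave them a value; the eosinophil, T and NK and sex-linked lists had none under the 75th percentile signal rule. Loess centring turned the sign of the MHC class II, IL-10 and reference medians, none of which stood apart. The list mean in place of the median ended the call for dendritic cell (0.34) and inflammasome genes (0.37) and made one for epithelial genes (0.51). The 75th percentile signal rule ended it for dendritic cell genes (0.36) and made one for lipid and cholesterol genes (-0.25). Without a signal rule, T and NK cell (0.04) and epithelial genes (0.088) stood apart as higher. Against unmatched random lists, oxidative stress (0.27), oxidative phosphorylation (0.20) and ribosomal protein genes (0.18) did so. Without the neutrophil and monocyte genes, the matrix remodelling median was -0.01 and its call ended, since 4 of its 9 genes at least 2-fold higher were left out. Of 148 named genes, 145 moved by less than the yardstick of 0.39 under all 8 settings that changed values or filters. Most of these settings could not move a gene with 1 probe set that far. Signal rules leave a gene's difference unchanged, median centring shifted all genes by 0.08, and the choice of probe set matters only for genes with several. With a floor at the 25th percentile, Stfa3, Ly6g and Dcpp2 had differences of 5.28, 5.47 and 4.24. Leaving out probe sets by ID ending and a pseudocount were not run, as the IDs carry no endings and the values are log2. No paired analysis was possible because each group had 1 array. Folds from a control or DSS signal under or just above its array's median are limited by background.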

Other observations

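Other than Arg1, Ly6c1 and Ly6c2, the genes given here lie outside all fixed lists. They were chosen after their values were seen, from ranks 13 to 60 in each direction, so they describe no gene group. Pglyrp1, a peptidoglycan recognition protein, read 6.43 in control and 10.08 in DSS, Slpi, a leukocyte protease inhibitor, 6.60 and 9.90, and Cfb, the complement factor B gene, 7.85 and 10.91. The interferon-inducible genes Slfn4 and Slfn1 had differences of 4.81 and 3.78, and Ifi205 and Ifi213 differences of 3.35 and 2.94. Arg2, the mitochondrial arginase, had a difference of 3.76, beside the 3.44 of Arg1, Upp1, a uridine phosphorylase, one of 4.11, and the glycogen phosphorylase gene Pygl one of 3.31. Also chosen after their values were seen, the probe sets shared by Ass1 and Gm5424 had differences of 3.32 and 3.26. Those shared by Ly6c1 and Ly6c2, entries of the fixed monocyte list that had no probe set of their own, had differences of 3.03 and 2.84.

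Among the genes lower in DSS, Ednrb, the endothelin receptor B gene, read 10.03 in control and 7.04 in DSS, Kitl, the ligand of the receptor KIT, 6.83 and 4.57, the cytokine gene Tslp 7.12 and 4.88, and Bmp2 8.63 and 6.64. The transcription factor gene Etv1 had a difference of -2.62, Fcrls one of -2.77 and Bank1 one of -2.36. The co-chaperone gene Bag3 and the heat shock gene Hspa1l had differences of -2.45 and -2.05.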
